A study of Mus musculus with 12 samples.

How the data were processed

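Nuclei of the left ventricle of male C57BL/6N and C57BL/6J mice, sorted by a DNA dye and run on the 10x Genomics 3′ v3.1 chemistry, gave 12 libraries in 4 groups of 3, control and HFpEF in each strain. The values used were the counts deposited by the authors, raw UMI counts per gene and nucleus with no normalization, together with the deposited cell table, which gives UMI and gene counts, the percent of UMIs from mitochondrially encoded genes, a cell type and one of 15 clusters for each nucleus. The column sums of the counts equalled the UMI numbers of the cell table, and the percent of mitochondrial UMIs in the deposited table equalled the value recomputed from the 13 mitochondrially encoded genes. All nuclei held 500 UMIs or more and under 5% mitochondrial UMIs. The submitters' processing notes name Cell Ranger 6.1.0, Seurat 5.0.1 and genome build mm10. The settings of alignment, whether intronic reads were counted, clustering, annotation and any correction for ambient RNA were not given in the sources used here. The treatment of doublets was not given either, and no doublet caller was run. The workbooks of differential genes that the labels mention were not used here. Each nucleus was assigned to its library by the library number of the cell table, and the strain and diet in the table matched the labels for 100% of nuclei. Genes carry symbols only, so no gene identifiers or positions are given.

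For each library and deposited cell type the UMIs of all nuclei were summed, so that the library, not the nucleus, was the replicate. A type's sum was used where the library held at least 20 nuclei of it, which all 12 libraries did in all 8 types. The fewest nuclei per library were 1360 for cardiomyocytes, 1768 for endothelial cells, 1700 for fibroblasts, 609 for mural cells, 314 for myeloid cells, 56 for lymphoid cells, 24 for neural cells and 112 for cluster 7. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, robust quasi-likelihood fit of 4 groups on all 12 libraries, Benjamini-Hochberg adjusted p under 0.05), with 14726 genes tested in cardiomyocytes, 12483 in endothelial cells, 13837 in fibroblasts, 11874 in mural cells, 11040 in myeloid cells, 4124 in lymphoid cells, 4959 in neural cells and 9748 in cluster 7. The contrasts were HFpEF minus control in each strain, C57BL/6N minus C57BL/6J averaged over the diets, and the difference of the 2 diet contrasts. Levels are TMM-scaled values of edgeR's cpm function (CPM), as mean and SD of 3 libraries. Fold changes are edgeR log2 values, with a standard error on the same scale. Complete separation of the libraries of 2 sides, used for naming, arises by chance for 10% of genes with 3 against 3 libraries and 0.217% with 6 against 6.

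Genes were named by a rule. In each type and contrast they had to pass the test, have a mean of at least 10 CPM, carry no predicted-gene symbol and, except for the interaction, show no overlap between the libraries of the 2 sides. Of these, the 10 with the largest fold change in each direction were named in cardiomyocytes and the 5 in other types, and all were named where 5 or fewer were called. Up to 4 members of each list with the smallest p, and Nnt in every type, were added. Some items that the rule or the cluster descriptions would name are not reported here. A set of 26 gene lists was written from general knowledge, none chosen on these libraries. They cover fatty acid use, PPAR-induced genes, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, antioxidant genes, the hypertrophic and fetal programme, calcium handling, sarcomere, unfolded protein response, mitochondrial stress, ketone and branched-chain amino acid use, sterol and fatty acid synthesis, nitric oxide and cGMP, the clock, immediate early and heat shock genes, and the interferon response. The others cover matrix and fibroblast activation, endothelial activation, endothelial lipid handling, endothelial growth and Notch, contractile and pericyte genes, resident, recruited and lipid-associated myeloid cells, and genes known to differ between the strains. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted within type and contrast. There were 18 lists in cardiomyocytes, 12 in endothelial cells, 9 in fibroblasts and 7 each in mural and myeloid cells. Members were also adjusted over the list alone. Markers of the other types were summed in each type as a measure of RNA from other cells.

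Shares of types were compared by exact permutation tests, two-sided, with diet permuted within strain and strain within diet (400 arrangements each, smallest p 0.005) and adjusted over 16 tests. Overlap of the 2 diet results, which share no libraries but take their spread from the same fit, was tested by Fisher's exact test. The comparisons, the gene lists, the naming rule and the main settings were chosen before the data were examined. So were these alternatives: RLE size factors, DESeq2 1.42.0, no filter on low counts, a replicate block, each library left out in turn, only nuclei with at least 1000 UMIs (91.4% of all), a covariate for RNA of other types, only the 6 libraries of a strain, an estimated correlation and fry (limma 3.58.1) for lists, a centred log ratio for shares, and an adjusted p under 0.1 for overlap. The alternatives added after seeing the data were the side of the first principal component as a term, the share of ribosomal protein RNA as a covariate, leaving out the 2% of nuclei with most UMIs, cardiomyocytes without cluster 14 and fibroblasts without cluster 6, cardiomyocytes without clusters 8 and 14, and leaving out the 3 libraries of high Arntl. Other splits of the libraries were all 10 for a diet contrast within a strain, and a draw of 60 in cardiomyocytes and 40 in other types for strain and interaction. The pipeline was tested on simulated data with 200 changed genes. In cardiomyocytes it recovered 85% of genes changed by 1 on the log2 scale and 99% of those changed by 2 for diet in C57BL/6N, 90% and 99% for diet in C57BL/6J, 97% and 100% for strain and 57% and 98% for the interaction. Of its calls there 3.16%, 5.50%, 5.29% and 5.49% in that order were genes left unchanged, and in endothelial cells and fibroblasts this ran from 1.98% to 6.15%. The simulated genes varied independently, with no component shared between libraries, and only genes at 10 CPM or more were changed. These shares therefore do not carry over to the real libraries, which share such a component. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for sums, shares and plots. Counts of 0 are given with the upper limit that 3 counts allow, which covers counting error alone.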

Results

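Nuclear RNA was sequenced from the left ventricle of male mice of 2 substrains, C57BL/6N and C57BL/6J, by droplet-based single-nucleus 3′ sequencing. In each substrain, mice on a control diet were set against mice given a high-fat diet and the nitric oxide synthase inhibitor L-NAME in the drinking water, a combined metabolic and hypertensive stress used to model heart failure with preserved ejection fraction (HFpEF). C57BL/6J mice carry a deletion in Nnt, the mitochondrial transhydrogenase named in the series title, so the design asks how each cell type of the ventricle responds to the model on the 2 backgrounds. Each of the 4 groups held 3 libraries, and the 12 libraries together held 97285 nuclei and 20580 genes. A library held between 6656 and 9656 nuclei, between 27549211 and 37590045 UMIs, and a median of 2035 to 2748 UMIs per nucleus. The mean number of nuclei per library was 8986 ± 639 (SD, n = 3) in C57BL/6N control, 8686 ± 627 in C57BL/6N HFpEF, 7011 ± 424 in C57BL/6J control and 7745 ± 590 in C57BL/6J HFpEF. The deposited annotation names 8 cell types. Endothelial cells (29358 nuclei), cardiomyocytes (24967) and fibroblasts (22995) were the most numerous, followed by mural cells (9263), myeloid cells (6719), a class deposited as mast cells (2168), lymphoid cells (1180) and neural cells (635). Cardiomyocyte nuclei were the deepest, with a median of 7631 UMIs, and gave between 13751192 and 21705641 UMIs per library. The labels give the same batch for every library and name 2 vendors without saying which supplied which mice, so that strain and vendor may be confounded.

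The leading genes of the deposited clusters named most types as the annotation does, with 4 exceptions that bear on later values. The class deposited as mast cells was led by the T-cell genes Skap1, Lef1 and Themis, and is called cluster 7 here. Cluster 6 of the fibroblast class (2465 nuclei) was led by Nrg1, Npr3, Vwf and Reln, genes of endocardium and lymphatic endothelium. Cluster 14 of the cardiomyocyte class (328 nuclei) was led by Mdga2, Pde8b and Rgs5, the last a pericyte gene, and cluster 8 (2016 nuclei) by the atrial genes Myl4, Nppa and Myl7. In addition, the 12 libraries fell on 2 sides of the first principal component, and the side of each library was the same in 5 of 5 types. C57BL/6N control replicates 2 and 3, C57BL/6J control replicate 3 and all 3 C57BL/6J HFpEF libraries lay on the high side, and the other 6 libraries on the low side. This component held 27.9% of the variance in cardiomyocytes, where scores ran from -37.8 to -18.1 on the low side and from 14.7 to 34.9 on the high side. A set of 3 C57BL/6J libraries, control replicates 1 and 2 and HFpEF replicate 1, had the highest Arntl and the lowest Per3 and Ciart, genes of the circadian clock, in all 5 types. In endothelial cells Arntl stood at 74.9 to 161.5 CPM (scaled UMI counts) in those libraries and at 3.00 to 29.9 in the other 9. In each strain 2 of the 3 control libraries lay on the other side of the component from the 3 HFpEF libraries.

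**Figure D1:**
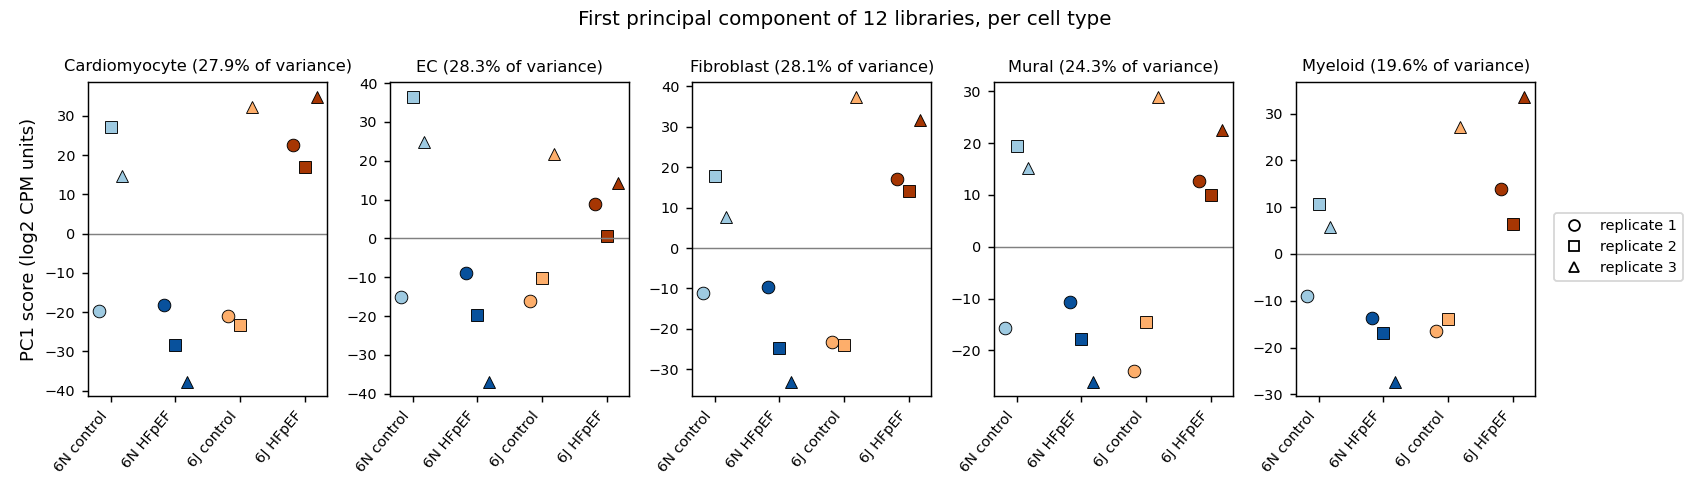
Score on the first principal component (vertical axis, log2 CPM units) of each library in 5 cell types, with the 4 groups on the horizontal axis (6N and 6J stand for C57BL/6N and C57BL/6J) and the replicate given by the marker. C57BL/6N control replicate 1 and C57BL/6J control replicate 3 lie apart from the rest of their groups in every panel, and the side of each library is the same in 5 of 5 types.

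Nnt itself was read in every type, and its level did not separate the strains. In cardiomyocytes it stood at 670 ± 15.2 CPM (SD, n = 3) in C57BL/6N control, 596 ± 73.9 in C57BL/6N HFpEF, 625 ± 145 in C57BL/6J control and 502 ± 30.7 in C57BL/6J HFpEF. The strain difference (C57BL/6N minus C57BL/6J) was a log2 fold change of 0.17 ± 0.11 (SE) in cardiomyocytes, with an adjusted p of 0.451 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the test used for all single genes here. In the other types the strain difference of Nnt ran from 0.13 in fibroblasts to 0.39 in neural cells, and none passed the test. The diet change of Nnt in cardiomyocytes was -0.17 ± 0.16 in C57BL/6N (adjusted p = 0.553) and -0.32 ± 0.16 in C57BL/6J (adjusted p = 0.291). That in endothelial cells of C57BL/6N was -0.73 ± 0.19 (adjusted p = 0.204), where cardiomyocyte markers took 0.404% ± 0.154 of endothelial UMIs in control and 0.258% ± 0.0637 in HFpEF. Where the Nnt reads lie in the gene is not given, and tags outside the deleted part, such as those of the 3′ end, check neither the deletion nor the strain labels.

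In C57BL/6N cardiomyocytes 13 genes rose and 12 fell with the HFpEF model, which asks how the strain with an intact Nnt responds. Cacna2d3, an auxiliary subunit of voltage-gated calcium channels, rose from 9.88 ± 2.04 CPM in control to 40.3 ± 5.74 in HFpEF (SD, n = 3 each), a log2 fold change of 2.03 ± 0.18 (SE; adjusted p = 0.000936). Gadd45g, a stress-induced growth arrest gene, rose from 11.2 ± 0.725 to 56.2 ± 31.3 CPM (2.33 ± 0.34, adjusted p = 0.0302). Sik1, a salt-inducible kinase, rose from 51.5 ± 3.78 to 149 ± 27.6 (1.53 ± 0.24, adjusted p = 0.0360). Abat, the enzyme that breaks down GABA, fell from 22.0 ± 1.68 to 3.91 ± 0.380 CPM (-2.49 ± 0.30, adjusted p = 0.00966). Ntn1, which encodes the guidance cue netrin 1, fell from 496 ± 62.0 to 177 ± 4.22 (-1.48 ± 0.14, adjusted p = 0.000936). Abca1, a cholesterol exporter, fell from 133 ± 13.6 to 55.5 ± 17.4 (-1.26 ± 0.18, adjusted p = 0.0302). Also higher were the matricellular gene Cyr61 (1.21), the kinase Pim1 (1.19), Atp5a1 of the ATP synthase (0.84), the RNA-binding gene Hnrnpdl (0.55) and the unnamed transcript RP24-362L9.2 (1.30). Lrtm1 was higher by 1.09, and since it lies within an intron of Cacna2d3 its own change is uncertain. Also lower were the transporter Mfsd7c (-1.30), the tetraspanin Tspan5 (-0.90), Phldb2 (-0.65), the angiotensin II receptor Agtr1a (-0.64), the motor Myo5a (-0.63), the mitochondrial leucyl-tRNA synthetase Lars2 (-0.59) and Ispd (-0.52). In all, 25 of 14726 genes passed the test, of which 9 higher and 10 lower ones met the rule for naming. An unadjusted p under 0.05 was reached by 3214, and DESeq2 called 934. Groups did not overlap for 3873 genes (26.3%, against 10% by chance). The count moved with single libraries. It was 1874, 6 and 4 without C57BL/6N control replicates 1, 2 and 3, and 8 and 3 without C57BL/6N HFpEF replicates 1 and 3. It was 8 and 340 without C57BL/6J control replicates 1 and 3, and 12, 11 and 7 without the C57BL/6J HFpEF replicates. Without C57BL/6N control replicate 1, that strain's controls all lie on the high side of the first principal component. Its HFpEF libraries lie on the low side, so the 1874 genes cannot be told apart from that side. Cacna2d3 and Ntn1 kept their calls in all 12 of these fits and Abat lost its call only without C57BL/6N HFpEF replicate 3. Each of the other named genes lost its call in 2 to 10 of these fits, among them without C57BL/6N HFpEF replicate 3. The count was 16 without cluster 14 and 94 without clusters 8 and 14, and it was 4 with the side of the first principal component as a term, an alternative chosen after seeing the data.

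**Figure D2:**
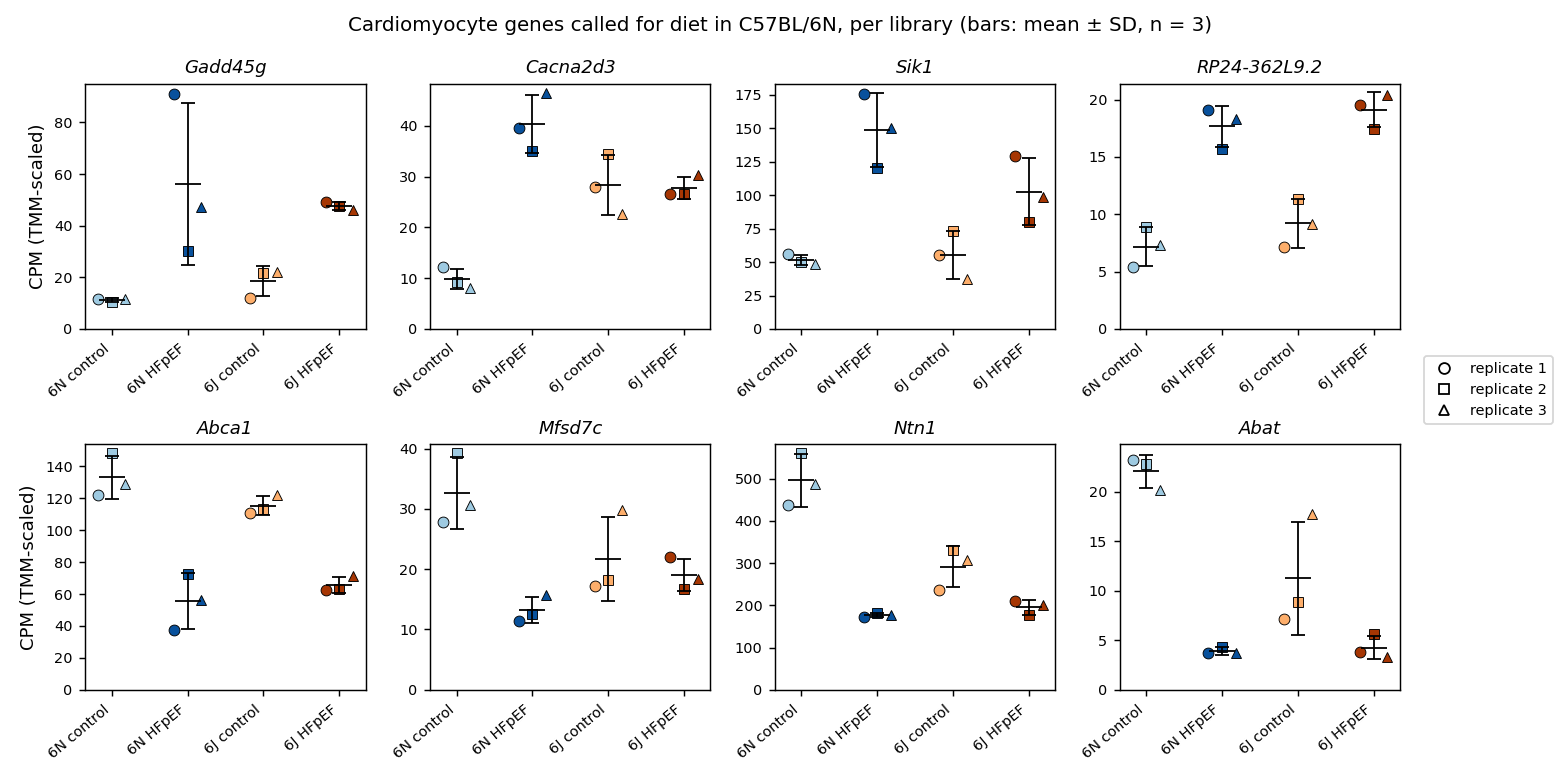
Cardiomyocyte level (vertical axes, TMM-scaled CPM) of the 4 genes with the largest rise and the 4 with the largest fall among those named for diet in C57BL/6N, per library in the 4 groups (horizontal axes, 6N and 6J standing for C57BL/6N and C57BL/6J), with bars at the mean and SD. Cacna2d3 stands near 10 CPM in C57BL/6N control alone, and Ntn1 falls from 496 to 177 CPM in C57BL/6N.

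Grouped by the fixed gene lists, C57BL/6N cardiomyocytes in HFpEF had higher oxidative phosphorylation, hypertrophic and immediate early genes and lower ketone and branched-chain amino acid genes at a preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.713 with an estimated correlation for each of the 4 lists), and Atp5a1 was the 1 member called over all genes. In the hypertrophic and fetal programme 17 of 19 members were higher (median log2 fold change 1.01). Among them were the skeletal actin Acta1 (3.37 ± 0.62, from 4.16 ± 2.12 to 42.5 ± 37.6 CPM), Ankrd23 (2.39 ± 0.70), the small heat shock protein Cryab (1.60 ± 0.37, from 174 ± 104 to 527 ± 137) and Mybpc2 (1.21 ± 0.33). These 4 were called adjusted over the list alone and none over all genes. Of the 36 oxidative phosphorylation genes 31 were higher (median 0.29). Atp5a1, Uqcrfs1 (0.62 ± 0.17), Ndufa10 (0.38 ± 0.10) and Uqcrc1 (0.29 ± 0.08) were called adjusted over the list alone. Immediate early and heat shock genes were higher in 17 of 18 members (median 0.83). Of these Btg2 (1.66 ± 0.41), Jun (1.50 ± 0.39), Atf3 (1.89 ± 0.52) and Hspa8 (1.02 ± 0.32) were called adjusted over the list alone. Of 28 glucose uptake and glycolysis genes 21 were higher (median 0.16). The 5 called adjusted over the list alone were the glycolytic genes Ldha (0.63), Pgam2 (1.13) and Hk2 (0.78), and Pdhb (0.51) and Pdha1 (0.30) of pyruvate dehydrogenase. Ketone and branched-chain amino acid genes were lower in 13 of 18 members (median -0.31). The 7 called adjusted over the list alone all belong to branched-chain amino acid breakdown, with Bcat2 (-0.67 ± 0.14), Ppm1k (-0.77 ± 0.20) and Bckdhb (-0.96 ± 0.26) in the lead. Mitochondrially encoded genes (11 of 13 higher, median 0.36), sarcomere genes (19 of 26 higher, median 0.23) and interferon response genes (22 of 26 lower, median -0.26) held no member called adjusted over the list alone.

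These 8 lists were the ones called in C57BL/6N cardiomyocytes of 18 run with camera at a preset correlation of 0.01. The adjusted p was 2.85e-07 for oxidative phosphorylation and for the hypertrophic programme, 0.000114 for immediate early genes, 0.00349 for ketone and branched-chain genes, 0.0210 for mitochondrially encoded genes, 0.0254 for interferon genes, 0.0301 for the sarcomere and 0.0302 for glycolysis. Each call was lost with an estimated correlation. The result was adjusted p = 0.713 with an estimated correlation for oxidative phosphorylation, the hypertrophic programme, immediate early, ketone and glycolysis genes, 0.761 for mitochondrially encoded and interferon genes, and 0.792 for the sarcomere. Leaving out 1 library ended 4 of the calls. Sarcomere and glycolysis genes lost theirs without C57BL/6N control replicate 3, C57BL/6N HFpEF replicate 1 or C57BL/6J control replicate 3 (adjusted p from 0.0586 to 0.309). Mitochondrially encoded genes lost theirs without C57BL/6N control replicates 2 or 3 or HFpEF replicate 3 (0.0801 to 0.138), and interferon genes without C57BL/6N control replicates 1 or 2 or HFpEF replicate 1 (0.0533 to 0.229). Fatty acid oxidation genes had a median of 0.00 and an adjusted p of 0.797. PPAR-induced genes had a median of 0.40 and an adjusted p of 0.105, with Retsat (0.72) called adjusted over the list alone. The calcium handling, unfolded protein response, mitochondrial stress, antioxidant, sterol synthesis, nitric oxide, clock and strain-difference lists were not called (adjusted p from 0.175 for sterol synthesis to 0.713). Members of them called adjusted over the list alone were Asph (0.65), Pde3a (-0.45), Pde4d (-0.63), Shmt2 (-0.88), Acaca (-0.75) and Srebf1 (-1.25).

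**Figure D3:**
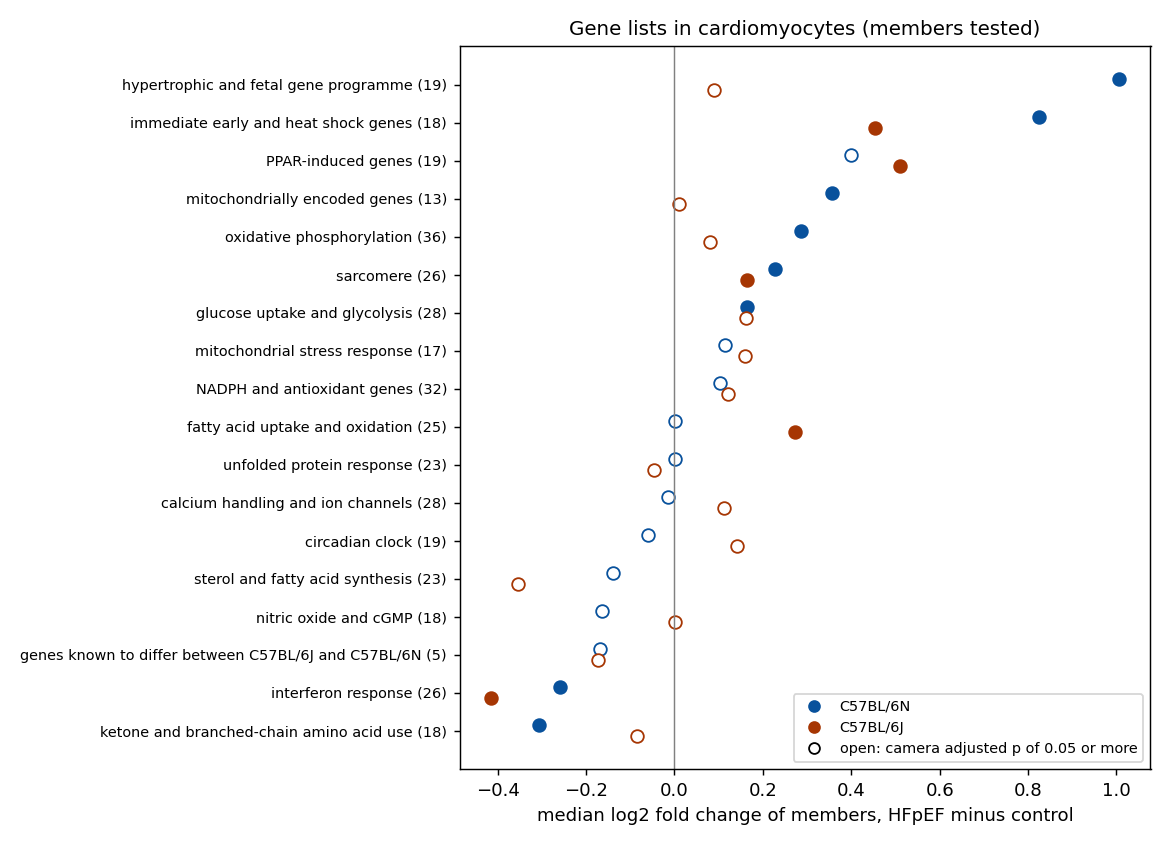
Median log2 fold change (horizontal axis, HFpEF minus control) of the members of 18 gene lists in cardiomyocytes of each strain, with the number of members tested beside each name and filled points for lists called by camera at a preset correlation. The hypertrophic and fetal programme stands at 1.01 in C57BL/6N and 0.09 in C57BL/6J, and fatty acid genes at 0.00 and 0.27.

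Outside cardiomyocytes, mitochondrially encoded genes were called higher with the model in 4 types of C57BL/6N at a preset correlation, and 1 single gene passed. These and the other list calls in those types were lost with an estimated correlation, with adjusted p from 0.138 to 0.686 with an estimated correlation. In endothelial cells all 13 members were higher (median 0.60), among them mt-Co1 (363 ± 115 to 681 ± 147 CPM, 0.91 ± 0.19) and mt-Cytb (97.2 ± 20.6 to 157 ± 27.0, 0.69 ± 0.15), and 8 were called adjusted over the list alone. The median was 0.57 in fibroblasts (11 of 13 higher, 8 called adjusted over the list alone), 0.61 in mural cells (12 of 12, 8 called) and 0.44 in myeloid cells (12 of 12, 1 called). The share of all UMIs from these genes was 0.109% ± 0.0325 (SD, n = 3) in C57BL/6N control, 0.157% ± 0.0189 in C57BL/6N HFpEF, 0.168% ± 0.0263 in C57BL/6J control and 0.153% ± 0.0104 in C57BL/6J HFpEF. In C57BL/6N the groups overlapped, with 0.146% in control replicate 1 and 0.135% to 0.169% in HFpEF. Control replicates 2 and 3, which lie on the high side of the first principal component apart from the other 4 C57BL/6N libraries, had 0.0934% and 0.0874%, so the rise goes with that side as well. Cytoplasmic RNA carried with the nuclei, which stays open for that side below, is not excluded as the source. A rise in 4 types therefore need not be 4 separate responses. Immediate early genes were higher in endothelial (17 of 18, median 0.58; Jun 0.79, Btg2 0.99 and Ier2 0.64 called adjusted over the list alone), mural (16 of 19, median 0.50) and myeloid cells (15 of 17, median 0.57). Recruited and antigen-presenting genes were higher in myeloid cells (11 of 12, median 0.45), with the chemokine receptor Ccr2 (1.52 ± 0.34) and the cytokine Tnf (1.84 ± 0.58) called adjusted over the list alone. The camera adjusted p for mitochondrially encoded genes was 2.58e-10 in endothelial cells, 6.84e-06 in fibroblasts, 1.92e-10 in mural and 2.26e-05 in myeloid cells, with a preset correlation. These calls were lost with adjusted p = 0.337, 0.686, 0.256 and 0.287 with an estimated correlation. For immediate early genes it was 7.17e-07 in endothelial, 3.50e-06 in mural and 0.000561 in myeloid cells, lost with adjusted p = 0.424, 0.389 and 0.456 with an estimated correlation. The recruited myeloid list had 6.66e-05, lost with adjusted p = 0.138 with an estimated correlation. The 1 gene called in these 7 types was Edil3, an integrin-binding matrix gene, which fell in myeloid cells from 176 ± 47.4 to 74.5 ± 9.48 CPM (-1.25 ± 0.17, adjusted p = 0.0163). Counts of 0 by edgeR stood beside 1892, 1710 and 1293 genes at an unadjusted p under 0.05 and 104, 126 and 39 called by DESeq2 in endothelial cells, fibroblasts and mural cells. They stood beside 209, 228 and 670 genes and 1, 0 and 5 by DESeq2 in lymphoid cells, neural cells and cluster 7. Without C57BL/6N control replicate 1, where diet and side of the first principal component coincide in that strain, the 7 types held 2049 called genes. Without C57BL/6J control replicate 3 they held 51. Without C57BL/6N HFpEF replicate 2 they held 4, without C57BL/6J control replicate 2 they held 3, and without C57BL/6N control replicate 2 or HFpEF replicate 3 they held 0.

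In C57BL/6J cardiomyocytes PPAR-induced and fatty acid genes were higher with the model as lists at a preset correlation. Both calls were lost with an estimated correlation (adjusted p = 0.624 with an estimated correlation), and no member was called over all genes. All 19 PPAR-induced genes tested were higher (median log2 fold change 0.51). Members called adjusted over the list alone included Angptl4 (1.67 ± 0.37), which inhibits lipoprotein lipase, the lipid droplet proteins Plin4 (0.98 ± 0.26, from 89.9 to 178 CPM) and Plin5 (0.89 ± 0.27), and the lipase Mgll (0.66 ± 0.20). Of 25 fatty acid uptake and oxidation genes 22 were higher (median 0.27). The transporter Slc27a1 (0.69 ± 0.16, from 237 to 381 CPM) and the dehydrogenase Acadvl (0.66 ± 0.12) were called adjusted over the list alone. Immediate early and heat shock genes were higher in 15 of 18 members (median 0.45), with the heat shock gene Hsph1 (1.28 ± 0.30) called adjusted over the list alone, and sarcomere genes in 20 of 26 (median 0.17, none called). Interferon genes were lower in 23 of 26 members (median -0.42), with Ifit2 (-1.52 ± 0.37) called adjusted over the list alone. Myeloid markers took 0.00204% ± 0.00119 of cardiomyocyte UMIs in C57BL/6J control and 0.000833% ± 9.68e-05 in HFpEF, fibroblast markers 0.0117% ± 0.00893 and 0.00401% ± 0.000461, and endothelial markers 0.0129% ± 0.00458 and 0.0105% ± 0.00212. The camera adjusted p was 7.15e-07 for PPAR-induced and 2.53e-05 for fatty acid genes, 0.000616 for immediate early and for interferon genes and 0.0125 for the sarcomere. All 5 calls were lost with an estimated correlation, with adjusted p = 0.662 with an estimated correlation for the sarcomere and adjusted p = 0.624 for the other 4. Those of immediate early and sarcomere genes were also lost without C57BL/6J control replicate 1 or HFpEF replicate 3 (adjusted p from 0.0586 to 0.491), and that of interferon genes without C57BL/6J HFpEF replicate 3 (0.119). The other 13 lists were not called, with adjusted p from 0.0751 for glycolysis and oxidative phosphorylation to 0.897 for mitochondrially encoded genes. The hypertrophic programme had a median of 0.09 and an adjusted p of 0.193. Members of these 13 called adjusted over the list alone included Pgk1 (0.64), Slc2a1 (-0.91), Nadk (0.58), Me1 (1.00), Pdia4 (-0.92), Hspd1 (0.54) and Scd2 (-2.44).

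Single genes called for diet in C57BL/6J cardiomyocytes were fewer, and 6 met the rule for naming. Fitm2, which promotes lipid droplet formation, rose from 34.6 ± 1.90 to 55.5 ± 5.40 CPM (0.68 ± 0.10). Cluh, which binds messages of mitochondrial proteins, rose from 103 ± 3.11 to 160 ± 9.56 (0.64 ± 0.09) and Uspl1 from 21.2 ± 3.01 to 37.0 ± 2.09 (0.80 ± 0.12), each with an adjusted p of 0.0407. The unnamed transcript RP23-455C13.7 rose by 0.79. Lrrc4b, a synaptic adhesion gene, fell from 19.8 ± 6.42 to 5.96 ± 0.581 CPM (-1.73 ± 0.27), and Ccnd2, which encodes cyclin D2, from 33.7 ± 6.49 to 16.7 ± 1.01 (-1.01 ± 0.16), with adjusted p of 0.0467. In all, 12 of 14726 genes passed the test, 6 in each direction. An unadjusted p under 0.05 was reached by 2784, DESeq2 called 653, and groups did not overlap for 3116 genes (21.2%, against 10% by chance). The 6 named genes lost their calls in 8 of the 12 fits that leave out 1 library. The count was 36, 3 and 0 without C57BL/6N control replicates 1, 2 and 3, and 19, 17 and 0 without the C57BL/6N HFpEF replicates. It was 0, 1 and 1149 without C57BL/6J control replicates 1, 2 and 3, and 0 without any C57BL/6J HFpEF replicate. It was 18 without cluster 14, 20 without clusters 8 and 14, and 0 with the side of the first principal component as a term. Without control replicate 3 the C57BL/6J controls lie on the low side of the first principal component and the HFpEF libraries on the high side. Diet and side coincide there, so the 1149 genes cannot be told apart from that side.

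Among the other types of C57BL/6J, edgeR called 7 genes in mural cells and 1 each in endothelial and lymphoid cells, where DESeq2 called 20, 36 and 0. The gene lists called in these types were each lost with an estimated correlation, with adjusted p from 0.289 to 0.762 with an estimated correlation. Adgrd1, an adhesion G protein-coupled receptor that is also among the leading genes of fibroblast cluster 5, fell from 28.6 ± 13.4 to 3.98 ± 2.22 CPM (-2.88 ± 0.42, adjusted p = 0.0166). The transcription factor Foxp2 fell from 131 ± 37.5 to 52.5 ± 2.24 (-1.34, adjusted p = 0.0127) and the GABA receptor subunit Gabra3 by 1.69 on the log2 scale. The glycosyltransferase A4galt rose from 69.7 ± 13.3 to 125 ± 13.5 (0.86, adjusted p = 0.0195). Myl3 (-1.15 ± 0.15, adjusted p = 0.00792) and Hrc (-1.46, adjusted p = 0.0453) also fell, and both are cardiomyocyte genes. Cardiomyocyte markers took 0.258% ± 0.0552 of mural UMIs in C57BL/6J control and 0.229% ± 0.0346 in HFpEF. Matrix genes were lower in 27 of 33 mural members (median -0.40), with Col1a1 (-1.74 ± 0.48), Loxl1 (-1.64 ± 0.46), Col14a1 (-1.55 ± 0.38) and Col8a1 (-0.63 ± 0.15) called adjusted over the list alone. Fibroblast markers took 0.0772% ± 0.0473 of mural UMIs in C57BL/6J control and 0.0383% ± 0.00344 in HFpEF. Contractile and pericyte genes were higher in 17 of 19 mural members (median 0.21, none called). In fibroblasts, sterol and fatty acid synthesis genes were lower in 22 of 23 members (median -0.58) and mitochondrially encoded genes in 13 of 13 (median -0.31), with no member called in either. Adipocyte markers took 0.00124% ± 0.00151 of fibroblast UMIs in C57BL/6J control and 0.000570% ± 0.000594 in HFpEF. Endothelial cells raised Adam23, an integrin ligand, from 20.5 ± 2.02 to 58.9 ± 1.70 CPM (1.53 ± 0.17, adjusted p = 0.00474, kept in all 12 fits that leave out 1 library). Lymphoid cells raised Igfbp7, a gene of vascular cells, from 89.0 ± 27.9 to 307 ± 39.5 (1.81 ± 0.33, adjusted p = 0.0361). There endothelial markers took 0.187% ± 0.0111 of lymphoid UMIs in control and 0.234% ± 0.0292 in HFpEF, and endocardial markers 0.00309% ± 0.000724 and 0.0149% ± 0.0138. Immediate early genes were called higher in endothelial cells (median 0.40, Dusp1 0.86), fibroblasts (0.11), mural cells (0.04) and myeloid cells (0.04), with Hsph1 called adjusted over the list alone in the last 3 types. Clock genes were called higher in endothelial (0.46), mural (0.25) and myeloid cells (0.38), calls lost with adjusted p = 0.517, 0.622 and 0.762 with an estimated correlation. C57BL/6J control replicates 1 and 2 and HFpEF replicate 1 stood apart in clock state (Arntl given above, as CPM of the raw total). Interferon genes were called lower in fibroblasts (-0.14) and myeloid cells (-0.19).

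These lists of C57BL/6J had the following tests. In mural cells the camera adjusted p was 2.21e-06 for matrix genes and 0.000258 for contractile genes (adjusted p = 0.289 with an estimated correlation for both), 0.0198 for immediate early and 0.0369 for clock genes (adjusted p = 0.622 with an estimated correlation for both). In fibroblasts it was 4.83e-05 for sterol synthesis and 0.000221 for mitochondrially encoded genes (adjusted p = 0.616 with an estimated correlation for both), 0.0237 for interferon and 0.0330 for immediate early genes (adjusted p = 0.710 with an estimated correlation for both). In endothelial cells immediate early genes had 1.75e-06 (adjusted p = 0.404 with an estimated correlation) and clock genes 0.0283 (adjusted p = 0.517 with an estimated correlation). In myeloid cells clock and interferon genes had 0.0189 and immediate early genes 0.0316, each lost with adjusted p = 0.762 with an estimated correlation. Clock and immediate early calls outside endothelial cells, and endothelial clock genes, were lost without C57BL/6J control replicate 1 (adjusted p from 0.497 to 0.939) and without HFpEF replicate 3 (0.245 to 0.911). Interferon calls were lost without C57BL/6J control replicates 1 or 3 or HFpEF replicates 1 or 3 (0.0637 to 0.812). Clock genes were also lost in endothelial cells without C57BL/6J control replicate 2 (0.0616) or HFpEF replicate 2 (0.0744), and in myeloid cells without HFpEF replicate 2 (0.159), and immediate early genes in the other 3 types without control replicate 3 (0.0765 to 0.564). Against the 18 list calls in C57BL/6J, 8 lists were called without C57BL/6J control replicate 1 and 8 without C57BL/6J HFpEF replicate 3, any newly called ones included. The 7 types held 9 called genes, of which 7 in mural cells. By edgeR, the calls numbered 0 in fibroblasts, myeloid cells, neural cells and cluster 7, where 1343, 872, 309 and 795 genes had an unadjusted p under 0.05 and DESeq2 called 13, 4, 0 and 4. Without C57BL/6J control replicates 2 and 3 the 9 became 1 and 975, and without C57BL/6J HFpEF replicates 2 and 3 they became 2 and 1. Without C57BL/6N control replicate 1 they became 22, and without C57BL/6N HFpEF replicates 1 or 3 or C57BL/6J control replicate 1 they became 6. In the fit with 975 genes, diet and the side of the first principal component coincide in C57BL/6J.

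Between the strains, averaged over the diets, 32 cardiomyocyte genes were lower and 16 higher in C57BL/6N than in C57BL/6J. The mitochondrially encoded mt-Nd3, a subunit of complex I, stood at 25.0 ± 3.97 and 25.6 ± 1.08 CPM in C57BL/6N control and HFpEF and at 42.6 ± 13.9 and 56.9 ± 14.9 in C57BL/6J (log2 fold change, C57BL/6N minus C57BL/6J, of -0.96 ± 0.16, adjusted p = 0.0395). Rap1gap, which inactivates the GTPase Rap1 (-0.89 ± 0.12), and the laminin chain Lamb2 (-0.61 ± 0.08) were lower in C57BL/6N with an adjusted p of 0.0291, and the fatty acid dehydrogenase Acadvl (-0.51 ± 0.08) with 0.0385. The cardiac homeobox gene Irx4 (-0.52), Fam109a (-0.68), Tmem150a (-0.60), Zfp512b (-0.58), Ybx2 (-0.55), Sh3glb2 (-0.54) and Hmg20b (-0.52) were also lower. None of the genes higher in C57BL/6N met the rule for naming. Among them, chosen after their values were seen, were Cygb (0.81), Ccdc80 (0.79), Scara5 (0.67) and Tnxb (0.66), which fibroblasts express. Fibroblast markers took 0.00955% ± 0.00319 of cardiomyocyte UMIs in C57BL/6N control, 0.0101% ± 0.000857 in C57BL/6N HFpEF, 0.0117% ± 0.00893 in C57BL/6J control and 0.00401% ± 0.000461 in C57BL/6J HFpEF. In all, 48 genes passed. An unadjusted p under 0.05 was reached by 2430, DESeq2 called 529, and strains did not overlap for 135 genes (0.917%, against 0.217% by chance). No list of 18 was called in cardiomyocytes, with a lowest adjusted p of 0.0784 for glycolysis, oxidative phosphorylation and interferon genes. Of 5 tested genes known to differ between the strains, Cyfip2 (-0.27), Ide (-0.24) and Fgfbp3 (0.57) were called adjusted over the list alone. The count was 93 and 0 without C57BL/6N control replicates 1 and 3, and 31 without replicate 2. It was 11 and 0 without C57BL/6N HFpEF replicates 2 and 3, 0 and 13 without C57BL/6J control replicates 1 and 2, and 3, 0 and 0 without the C57BL/6J HFpEF replicates. It was 505 without the 3 libraries of high Arntl, a fit in which all 3 C57BL/6J libraries left lie on the high side of the first principal component, so that strain and side partly coincide.

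In fibroblasts, matrix genes as a list were lower in C57BL/6N than in C57BL/6J at a preset correlation, a call lost with adjusted p = 0.129 with an estimated correlation. The other lists called between the strains outside cardiomyocytes were lost as well, with adjusted p from 0.158 to 0.558 with an estimated correlation. Of 40 members 34 were lower (median -0.21), with Col12a1 (-1.89 ± 0.28), Postn (-1.55 ± 0.30), Cilp (-1.10 ± 0.26), Col6a1 (-0.60) and Mmp2 (-0.41) called adjusted over the list alone and none over all genes. Sterol synthesis genes were lower in 21 of 23 members (median -0.27), mitochondrially encoded genes in 9 of 13 (median -0.16) and interferon genes in 22 of 30 (median -0.10). Fatty acid genes were higher in 19 of 24 (median 0.14; Fabp3 0.77) and PPAR-induced genes in 13 of 18 (median 0.21). Cardiomyocyte markers took 0.270% ± 0.105 of fibroblast UMIs in C57BL/6N control, 0.193% ± 0.0363 in C57BL/6N HFpEF, 0.189% ± 0.0415 in C57BL/6J control and 0.151% ± 0.00738 in C57BL/6J HFpEF, and Fabp3 is a cardiomyocyte gene. Adipocyte markers, in the same order, took 9.60e-06% ± 1.66e-05, 0.000145% ± 0.000240, 0.00124% ± 0.00151 and 0.000570% ± 0.000594. In endothelial cells interferon genes were lower in 26 of 28 members (median -0.18; Irf7 -0.78 and Ifit2 -0.44 called adjusted over the list alone). Growth and Notch genes were lower in 17 of 22 (median -0.14; Dll4, a Notch ligand, -0.34) and immediate early genes in 14 of 18 (median -0.22). Fatty acid genes were higher in 23 of 24 (median 0.20; Fabp3 0.66, Acaa2 0.40 and Acadvl 0.42) and PPAR-induced genes in 12 of 16 (median 0.17). Tcap, a sarcomere gene called over all genes (0.97 ± 0.13), is likewise a cardiomyocyte gene. Cardiomyocyte markers took 0.404% ± 0.154 of endothelial UMIs in C57BL/6N control, 0.258% ± 0.0637 in C57BL/6N HFpEF, 0.280% ± 0.0475 in C57BL/6J control and 0.201% ± 0.00746 in C57BL/6J HFpEF. Mitochondrially encoded genes were lower in C57BL/6N in endothelial (10 of 13, median -0.33), mural (9 of 12, median -0.34) and myeloid cells (9 of 12, median -0.20), but mt-Nd6 was higher (0.85 in endothelial cells, 1.21 in fibroblasts). Mitochondrially encoded genes together took 0.132% and 0.119% of endothelial UMIs in C57BL/6N control replicates 2 and 3. Their share was 0.185% to 0.269% in the other C57BL/6N libraries and 0.229% to 0.274% in C57BL/6J. In myeloid cells resident macrophage genes were lower in 13 of 16 members (median -0.24), with the lectin Cd209f (-1.63 ± 0.37) called adjusted over the list alone, and interferon genes in 21 of 26 (median -0.19).

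Single genes called for strain outside cardiomyocytes numbered 11. Endothelial cells had lower mt-Nd3 (-0.83 ± 0.11) and Scarf1, a scavenger receptor (-0.46 ± 0.06), and higher Tcap in C57BL/6N, all with an adjusted p of 0.0128. Myeloid cells had lower complement C4b (-1.02) and the lectin Cd209g (-2.21, from 2.05 and 8.00 CPM in C57BL/6N to 15.3 and 24.0 in C57BL/6J), with an adjusted p of 0.0444. Neural cells had lower Dct, an enzyme of melanin synthesis (-7.44 ± 1.03, with 3.98 and 2.88 CPM in C57BL/6N and 810 and 730 in C57BL/6J), and the adenylate cyclase Adcy2 (-1.74 ± 0.27), with an adjusted p of 0.0441. At least 2 Dct UMIs were found in 18 of 335 neural nuclei of C57BL/6J and in 0 of 300 of C57BL/6N, which allows a share of up to 1%. By edgeR 0 genes passed in fibroblasts, mural cells, lymphoid cells and cluster 7, where 1446, 852, 225 and 842 had an unadjusted p under 0.05 and DESeq2 called 97, 11, 0 and 13. The camera adjusted p in fibroblasts was 1.31e-07 for matrix genes (adjusted p = 0.129 with an estimated correlation), 8.31e-05, 0.000179 and 0.00406 for fatty acid, sterol and PPAR-induced genes (adjusted p = 0.251 with an estimated correlation for the 3). It was 0.00406 for mitochondrially encoded genes (adjusted p = 0.426) and 0.0128 for interferon genes (adjusted p = 0.558). In endothelial cells it was 6.99e-08, 3.01e-07 and 3.11e-06 for interferon, mitochondrially encoded and fatty acid genes (adjusted p = 0.274 with an estimated correlation for the 3). It was 0.00263 for growth and Notch genes (adjusted p = 0.158), 0.00281 for immediate early genes (adjusted p = 0.402) and 0.0126 for PPAR-induced genes (adjusted p = 0.376). Mitochondrially encoded genes had 1.61e-10 in mural cells (adjusted p = 0.251 with an estimated correlation). In myeloid cells resident macrophage genes had 0.00118, and interferon and mitochondrially encoded genes 0.00417, each lost with adjusted p = 0.498 with an estimated correlation. Some of these calls were lost without 1 library. In endothelial cells PPAR-induced genes were lost without C57BL/6N control replicate 2 or C57BL/6J HFpEF replicate 1 (adjusted p 0.160 and 0.107), and immediate early genes without C57BL/6J control replicate 2 (0.218). In fibroblasts PPAR-induced genes were lost without C57BL/6N control replicate 2 (0.0673), mitochondrially encoded genes without C57BL/6J control replicate 1 (0.0811), and interferon genes without that library, C57BL/6N control replicate 3, C57BL/6N HFpEF replicate 1 or C57BL/6J HFpEF replicate 2 (0.0811 to 0.302). In myeloid cells mitochondrially encoded genes were lost without C57BL/6N control replicate 3, C57BL/6N HFpEF replicate 2 or C57BL/6J control replicate 1 (0.0596 to 0.0910), and interferon genes without C57BL/6N control replicate 3, C57BL/6N HFpEF replicate 1, C57BL/6J control replicate 3 or C57BL/6J HFpEF replicate 2 (0.0542 to 0.158). The endothelial growth and Notch list was the 1 call of these that fry also made (adjusted p = 0.0403). Without C57BL/6N control replicates 1, 2 and 3 the 11 genes became 123, 5 and 1, and without C57BL/6N HFpEF replicates 1, 2 and 3 they became 7, 5 and 0. Without C57BL/6J control replicate 3 they became 19, and without C57BL/6J HFpEF replicates 2 and 3 they became 7 and 0.

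The response to the model was tested for a difference between the strains by the interaction, in which a positive value means a higher change in C57BL/6N. Cacna2d3 in cardiomyocytes rose more in C57BL/6N (2.06 ± 0.25, adjusted p = 0.0299), and its level in C57BL/6J was 28.3 ± 5.96 CPM in control and 27.8 ± 2.15 in HFpEF. In myeloid cells Mmp12, a macrophage elastase (3.00 ± 0.55), Hsf3 (2.54 ± 0.45), Zeb2os (1.67 ± 0.31), the oxysterol receptor Gpr183 (1.49 ± 0.27) and Cybb, the catalytic subunit of the phagocyte oxidase (1.26 ± 0.23), had a positive interaction, with an adjusted p of 0.0450. Cybb stood at 231 and 296 CPM in C57BL/6N control and HFpEF and at 256 and 137 in C57BL/6J. Zeb2os is antisense to Zeb2, so its own level is uncertain. Fibroblast markers took 0.0744% ± 0.0227 of the UMIs of cluster 7 in C57BL/6N control, 0.0960% ± 0.0157 in C57BL/6N HFpEF, 0.109% ± 0.0575 in C57BL/6J control and 0.0589% ± 0.0178 in C57BL/6J HFpEF, and Adgrd1 is among the leading genes of fibroblast cluster 5. Cluster 7 had positive interactions of Adgrd1 (2.75 ± 0.42) and Igf2r (1.50 ± 0.23) with an adjusted p of 0.0121, and of Slc7a15 (5.06 ± 0.91) and Gm15581 (2.37) with 0.0440. The lists called for the interaction at a preset correlation were each lost with an estimated correlation, with adjusted p from 0.328 to 0.927 with an estimated correlation. Of them, fatty acid genes were lower in the interaction in cardiomyocytes (19 of 25 members lower, median -0.28, with Slc27a1 at -1.29 ± 0.22 called adjusted over the list alone). Hypertrophic genes (16 of 19 higher, median 0.84, none called) and oxidative phosphorylation genes (24 of 36 higher, median 0.22, with Atp5a1 0.89, Cox7c 1.32 and Uqcrfs1 0.86 called adjusted over the list alone) were higher. Mitochondrially encoded genes were higher in the interaction in endothelial cells (13 of 13, median 0.78), fibroblasts (12 of 13, 0.91), mural cells (12 of 12, 0.82) and myeloid cells (12 of 12, 0.61), calls lost with adjusted p = 0.492, 0.393, 0.415 and 0.458 with an estimated correlation. Matrix genes of mural cells (27 of 33, 0.29) and recruited myeloid genes (11 of 12, 0.59, H2-Eb1 called adjusted over the list alone at 0.86) were also higher, and clock genes of myeloid cells lower (13 of 18, -0.43). Mitochondrially encoded genes took 0.0900% and 0.0805% of fibroblast UMIs in C57BL/6N control replicates 2 and 3. The other C57BL/6N libraries held 0.130% to 0.196%. C57BL/6J control replicates 1 and 2 held 0.213% and 0.173%, and the other C57BL/6J libraries 0.133% to 0.150%. Cytoplasmic RNA carried with the nuclei is not excluded as the source of these interactions.

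For the interaction, 1 gene passed in cardiomyocytes, where 2892 had an unadjusted p under 0.05 and DESeq2 called 558. There were 10 in myeloid cells and 4 in cluster 7. By edgeR 0 passed in endothelial cells, fibroblasts, mural, lymphoid and neural cells, where 1725, 2119, 1347, 325 and 464 had an unadjusted p under 0.05 and DESeq2 called 110, 208, 27, 1 and 1. The camera adjusted p in cardiomyocytes was 0.0168 for fatty acid and hypertrophic genes and 0.0485 for oxidative phosphorylation, each lost with adjusted p = 0.927 with an estimated correlation. For mitochondrially encoded genes it was 1.38e-08 in endothelial cells, 5.09e-08 in fibroblasts, 3.84e-08 in mural and 0.000536 in myeloid cells, lost with adjusted p = 0.492, 0.393, 0.415 and 0.458 with an estimated correlation. It was 0.0104 for mural matrix genes, 0.00151 for recruited myeloid and 0.0274 for clock genes, lost with adjusted p = 0.827, 0.328 and 0.668 with an estimated correlation. The Cacna2d3 interaction was called without C57BL/6N control replicate 1, C57BL/6N HFpEF replicate 2 or C57BL/6J control replicate 3, with counts of 1283, 1 and 1272, and lost without each of the other 9 libraries, with a count of 0. In the 7 other types the 14 genes became 1172, 2 and 0 without C57BL/6N control replicates 1, 2 and 3, and 4 and 0 without C57BL/6N HFpEF replicates 2 and 3. They became 1, 1 and 1601 without the C57BL/6J control replicates, and 8, 8 and 0 without the C57BL/6J HFpEF replicates. Diet and the side of the first principal component coincide in C57BL/6N without control replicate 1, and in C57BL/6J without control replicate 3. The counts of 1283, 1172, 1272 and 1601 come from those fits. Among the lists of cardiomyocytes, all 3 interactions were lost without C57BL/6N control replicate 2 (adjusted p 0.101, and 0.145 for oxidative phosphorylation) or HFpEF replicate 1 (0.113). Fatty acid genes were also lost without C57BL/6J control replicate 3 (0.0880) or HFpEF replicate 2 (0.337), and oxidative phosphorylation without C57BL/6N control replicate 3, C57BL/6N HFpEF replicate 3, C57BL/6J control replicates 2 or 3 or C57BL/6J HFpEF replicate 1 (0.0773 to 0.196). Mural matrix genes were lost without C57BL/6J control replicate 1 (0.340) or HFpEF replicate 2 (0.101). Myeloid clock genes were lost without C57BL/6N control replicates 1 or 3, C57BL/6N HFpEF replicate 1, C57BL/6J control replicate 1 or C57BL/6J HFpEF replicates 2 or 3 (0.0546 to 0.424).

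Whether the strains shared their diet genes was asked directly in cardiomyocytes. The 1 gene called higher in both was the predicted gene Gm12153, chosen after its values were seen (1.31 in C57BL/6N and 1.05 in C57BL/6J), against 0.00530 expected (Fisher's exact p = 0.00529, two-sided). The count lower in both was 0, against 0.00489 expected. Of the genes called in C57BL/6N, 9 of 13 higher ones and 12 of 12 lower ones had the same sign in C57BL/6J. Abca1 stood at 115 and 65.8 CPM in C57BL/6J control and HFpEF, Ntn1 at 291 and 196 and Gadd45g at 18.5 and 47.6, and none of these 3 was called in C57BL/6J or in the interaction. Across all genes tested, which are not independent replicates, the log2 fold changes of the strains had a Pearson correlation of -0.0185 in cardiomyocytes, -0.0240 in endothelial cells and -0.208 in fibroblasts. C57BL/6N control replicates 2 and 3 lay on the high side of the first principal component and the C57BL/6N HFpEF libraries on the low side. In C57BL/6J, control replicates 1 and 2 lay on the low side and the HFpEF libraries on the high side. The component thus enters the diet contrasts with opposite sign, which these correlations cannot tell from unlike diet responses. At an adjusted p of 0.1 the strains shared 9 higher genes, against 2.92 expected (Fisher's exact p = 0.00261), and 16 lower genes, against 1.62 expected (Fisher's exact p = 5.0e-12). Of the genes called in C57BL/6N at that threshold, 190 of 398 higher ones and 206 of 268 lower ones had the same sign in C57BL/6J. Both diet results come from a single fit with a shared spread per gene, and Fisher's test takes genes as independent. Its p-values here can therefore be too small and do not measure how far the responses agree.

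Tissue make-up was compared as the share of each type among a library's nuclei. Cardiomyocytes made up 24.2% in control and 27.3% in HFpEF libraries (exact permutation p = 0.16, two-sided). Mural cells made up 10.4% and 9.08% in C57BL/6N control and HFpEF and 9.78% and 8.81% in C57BL/6J, a difference of -1.13 points (exact permutation p = 0.02, adjusted p = 0.32). As a centred log ratio the mural difference was -0.0418 (exact permutation p = 0.44, adjusted p = 0.809), with -0.166 in C57BL/6N and 0.0825 in C57BL/6J. By the exact permutation test 0 of 16 tests passed after adjustment, 1 had an unadjusted p under 0.05, and the 400 arrangements allow no p below 0.005. A single type could therefore not pass after adjustment over 16 tests, so the count of 0 does not show an unchanged make-up.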

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

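All tests of explanations and of other splits in this part were chosen only after the result they concern was seen.

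The results listed here were picked because the diet effect differed between the strains by the interaction test, in which a positive value means a higher change in C57BL/6N. In cardiomyocytes this was Cacna2d3 (2.06 on the log2 scale). In myeloid cells it was Mmp12 (3.00), Hsf3 (2.54), Zeb2os (1.67), Gpr183 (1.49) and Cybb (1.26), and in cluster 7 Adgrd1 (2.75), Gm15581 (2.37), Slc7a15 (5.06) and Igf2r (1.50). Among the lists, with their median interaction, it was fatty acid (-0.28), oxidative phosphorylation (0.22) and hypertrophic genes (0.84) in cardiomyocytes, mitochondrially encoded genes in endothelial cells (0.78), fibroblasts (0.91), mural cells (0.82) and myeloid cells (0.61), matrix genes in mural cells (0.29), and clock (-0.43) and recruited genes (0.59) in myeloid cells. Chance could not be excluded for these results. Of the splits of the libraries, 7 of 60 called at least the 1 gene in cardiomyocytes (highest other 403), 8 of 40 at least the 14 genes in other types (highest other 389), and 37 of 40 at least the 10 lists (highest other 29). With the side of the first principal component as a term the other types held 1 called gene and cardiomyocytes 0. The count of 14 also became 1172 without C57BL/6N control replicate 1 and 1601 without C57BL/6J control replicate 3. In those fits diet and the side of the component coincide within the strain of the library left out.

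For the other results, 2 of a draw of 60 splits, the real one included, reached the 48 strain genes of cardiomyocytes. This share is under 0.05 only without adjustment over the 12 results so tested, so chance was not excluded. The highest other split called 3197 genes, many times the real count, which points to a structure of the samples other than strain. The count of 48 was itself unstable, at 5 with a replicate block and at 0 without C57BL/6N control replicate 3, C57BL/6N HFpEF replicate 3, C57BL/6J control replicate 1 or C57BL/6J HFpEF replicates 2 or 3 (by edgeR, with 2430 genes at an unadjusted p under 0.05 and 529 called by DESeq2 with all libraries). It was at most 93 without any other single library. Chance could not be excluded for the 11 strain genes of other types (4 of 40 splits, highest other 5474, again a structure of the samples) or for the 16 strain lists (26 of 40, highest other 33). The 10 splits of a diet contrast within a strain are too few for a share under 0.05. The 25 genes of C57BL/6N cardiomyocytes had a highest other of 0 (1 of 10 splits as large), the 12 of C57BL/6J a highest other of 126 (2 of 10), the 1 and 9 genes of other types highest others of 395 (5 of 10) and 762 (2 of 10), and the 16 and 18 lists highest others of 23 (5 of 10) and 28 (6 of 10). Splits with 126, 395 and 762 genes, several times the real counts, likewise point to a structure of the samples.

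The first pattern weighed is the 2 sides of the first principal component, on which C57BL/6N control replicate 1 and C57BL/6J control replicate 3 lie apart from their groups. A swap of the labels of those libraries stays open. Genes separating the strains in the other 10 libraries, about 50 in each of 6 types, placed them nearer the labelled strain in 389 of 598 placements (65.1%), 1 per gene, type and library, with 51.0% to 78.0% in a type and library. This cannot decide, since the component itself favours such placements. The other C57BL/6N libraries lie mostly on the low side, as C57BL/6N control replicate 1 does. The other C57BL/6J libraries lie mostly on the high side, as C57BL/6J control replicate 3 does. The placements also come from 2 libraries and are not independent. A response of strain by diet as the whole cause was argued against by the pattern itself, not by a separate test. By its definition, 2 of 12 libraries lie on the other side than the rest of their group. A library batch or cytoplasmic RNA carried with the nuclei may account for it and stays open. Ribosomal protein RNA separated the sides without overlap in 2 of 5 types (in endothelial cells at most 0.381% of UMIs on the high side and at least 0.396% on the low side) and overlapped in the others, while the labels give 1 batch for all libraries, and a biological difference between animals was not tested.

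The second pattern is the clock state of C57BL/6J control replicates 1 and 2 and HFpEF replicate 1. An effect of diet in C57BL/6J as the whole cause was argued against by the pattern itself, not by a separate test. Arntl in endothelial cells differed 18.7-fold between the highest and the lowest of the 3 C57BL/6J HFpEF libraries, and high Arntl defines the pattern. Different times of tissue collection may account for it and stay open, since the labels give no collection times. Dbp and Per2, which do not define the pattern here but follow the same clock, were both lowest in these 3 libraries in 4 of 5 types, and Dbp was not in cardiomyocytes, but any other cause that moves the clock would give this too.

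The third pattern is the nuclei with melanocyte genes in C57BL/6J, seen from the strain difference of Dct in neural cells. They were 18 of 335 neural nuclei (5.37%, from 1 to 6 in each of the 6 C57BL/6J libraries) with at least 2 Dct UMIs, against 0 of 300 in C57BL/6N. Free RNA was argued against, since 72.2% of the 18 also held a UMI of Tyr, 14 one of Pmel and 14 one of Trpm1, against 0, 2 and 1 of the other 617 neural nuclei, at median depths of 2490 and 2886 UMIs, and 5.37% against the 1% that a count of 0 allows argued against too few C57BL/6N nuclei. A Dct UMI alone is poor evidence, since 4.92% of C57BL/6N and 6.86% of C57BL/6J cardiomyocytes held one (median depths 7272 and 8008 UMIs), against 1.33% and 6.27% of neural nuclei (2802 and 2889 UMIs). More atrial or valve tissue in the C57BL/6J samples could be a source and stays open, although the atrial cluster 8 differed by 0.265 points in the other direction (2.20% of nuclei in C57BL/6N, 1.93% in C57BL/6J), and a strain difference in cardiac melanocytes was not tested otherwise.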

How the results depend on the processing

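The alternatives with the first principal component, ribosomal protein RNA, the top 2% of nuclei, clusters or high-Arntl libraries were chosen only after the results were seen. Counts are given as cardiomyocytes, then the 7 other types together, and where none is given the count stayed within 1.5 times. For diet in C57BL/6N (25 and 1), the counts were 13 with RLE factors, 158 in other types without a filter, 12 and 4 with a replicate block, 3 and 14 with the covariate for RNA of other types, and 9 and 58 with the 6 libraries of that strain. They were 4 and 10 with the component, 7 and 2 with ribosomal RNA, 13 and 4 without the top 2%, 16 without clusters 6 and 14, 94 without clusters 8 and 14, 81 in other types without high Arntl, and 934 and 301 with DESeq2. For diet in C57BL/6J (12 and 9) they were 30 in cardiomyocytes with RLE factors, 31 and 286 without a filter, 0 and 21 with the block, 0 and 138 with the covariate, and 0 in cardiomyocytes with 6 libraries. They were 0 and 16 with the component, 0 and 27 with ribosomal RNA, 20 without clusters 8 and 14, 0 and 3 without high Arntl, and 653 and 77 with DESeq2. For strain (48 and 11) they were 5 and 7 with the block, 275 in other types without a filter, 17 and 115 with the covariate, 49 in other types with the component, 588 and 87 with ribosomal RNA, 505 and 1101 without high Arntl, and 529 and 226 with DESeq2. For the interaction (1 and 14) they were 438 in other types without a filter, 0 and 2 with the block, 6 in other types with 1000 UMIs, 0 and 118 with the covariate, 0 and 1 with the component and with ribosomal RNA, 0 and 0 without high Arntl, and 558 and 401 with DESeq2. The fits without high Arntl hold 1 C57BL/6J control library, with the spread taken from the other groups, and C57BL/6J libraries of the high side of the component alone, so their counts decide nothing about the clock. Leaving out 1 library gave 3 to 1874 and 0 to 2049 for diet in C57BL/6N, 0 to 1149 and 1 to 975 for diet in C57BL/6J. It gave 0 to 93 and 0 to 123 for strain, and 0 to 1283 and 0 to 1601 for the interaction, with the highest values without C57BL/6N control replicate 1 or C57BL/6J control replicate 3, as the results give by library. Without either of these libraries, diet and the side of the component coincide within its strain. Of 16, 18, 16 and 10 list calls, 0 held with an estimated correlation and 0, 0, 1 and 0 with fry. The number of lists called, newly called ones included, was 14 to 19, 8 to 26, 15 to 24 and 7 to 14 with 1 library out. The component raised the number of strain lists called to 27. Overlap went from 1 to 25 genes at an adjusted p of 0.1, shares stayed at 0 called (0 to 0 with 1 library out), and Nnt moved within its spread. For shares this says little about stability, since a single type could not pass after adjustment. Over 122 single genes and lists, 1528 values kept their call, 898 lost it and 6 turned direction. These were, with the component, the interaction of oxidative phosphorylation (adjusted p = 0.257, over all alternatives 7.23e-05 to 0.927) and hypertrophic genes (0.804, 0.000103 to 0.927) in cardiomyocytes. The others were, with the component, those of mural matrix genes (0.200, 2.63e-06 to 0.827) and of myeloid clock genes (0.493, 4.33e-05 to 0.742), and, without C57BL/6J control replicate 1, immediate early genes for diet in C57BL/6J in fibroblasts (0.781, 1.06e-07 to 0.911) and mural cells (0.939, 2.45e-08 to 0.939). The cause of these moves was not tested. Replicate numbers did not pair the libraries in all groups (correlations from -0.253 to 0.312 in cardiomyocytes). Between C57BL/6J control and HFpEF the correlations were positive, at 0.256, 0.128 and 0.312 for replicates 1, 2 and 3. A pairing of those libraries is not excluded. In the simulation, which held no component shared between libraries, 57% of interactions of 1 on the log2 scale were recovered in cardiomyocytes. Lymphoid and neural cells held as few as 56 and 24 nuclei per library.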

Other observations

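The tests of this part were planned for the gene lists, and the comparisons of single clusters were chosen only after the data were seen.

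Myeloid nuclei showed a lipid-handling gene in both strains that no called list describes. Plin2, which coats lipid droplets, stood at 68.0 ± 10.6 CPM (SD, n = 3) in C57BL/6N control and 102 ± 5.77 in HFpEF (log2 fold change 0.58 ± 0.14) and at 71.9 ± 4.08 and 102 ± 5.14 in C57BL/6J (0.52 ± 0.15). It was called adjusted over the lipid-associated macrophage list alone in both, not over all genes. Lgals3, the galectin of activated macrophages, was at 27.6 ± 9.39 and 53.9 ± 5.81 CPM in C57BL/6J (1.04 ± 0.28), also called adjusted over the list alone, and at 30.5 ± 11.2 and 34.5 ± 7.00 in C57BL/6N. Cd9 (0.55), Pparg (0.50) and Cd36 (0.32) were higher in C57BL/6N than in C57BL/6J adjusted over the list alone. Cd36 is also a gene of endothelial cells and cardiomyocytes. Endothelial markers took 0.0260% ± 0.00545, 0.0242% ± 0.00479, 0.0234% ± 0.00988 and 0.0161% ± 0.00727 of myeloid UMIs in C57BL/6N control and HFpEF and C57BL/6J control and HFpEF, and cardiomyocyte markers 1.10% ± 0.227, 0.899% ± 0.129, 0.847% ± 0.229 and 0.991% ± 0.349. The list as a whole was not called in any contrast (adjusted p from 0.253 to 0.905).

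Nitric oxide and cGMP genes, which the L-NAME in the model addresses, were not called as a list in cardiomyocytes, endothelial or mural cells in any contrast (adjusted p from 0.299 to 0.885). Single members called adjusted over the list alone were the inducible synthase Nos2 in mural cells of C57BL/6J (-1.80 ± 0.50 with HFpEF) and between strains in endothelial cells (-0.42 ± 0.10), and the natriuretic peptide receptor Npr1 in cardiomyocytes between strains (0.58 ± 0.14). Endothelial activation genes (adjusted p from 0.325 to 0.868, written for adhesion and inflammatory molecules such as Vcam1 and Icam1) and endothelial lipid handling genes (from 0.0553 for diet in C57BL/6J to 0.762) were not called, nor was the unfolded protein response in any of 3 types (from 0.219 to 0.900). In endothelial cells of C57BL/6N, Slc27a1 (-1.62), Srebf1 (-0.69) and Acaca (-0.42) were lower and Ech1 (0.47) higher with HFpEF, each adjusted over its list alone. Slc27a1 is also a cardiomyocyte gene, and cardiomyocyte markers took 0.404% ± 0.154 of endothelial UMIs in C57BL/6N control and 0.258% ± 0.0637 in HFpEF.

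Among single clusters, cluster 6 of the fibroblast class, with endocardial and lymphatic genes, held 12 called genes for diet in C57BL/6N, 0 for diet in C57BL/6J (603 at an unadjusted p under 0.05 by edgeR, with DESeq2 not run there), 3 for strain and 6 for the interaction. The rest of the fibroblasts held 0 in each contrast by edgeR, with 1633, 1536, 1397 and 2023 genes at an unadjusted p under 0.05, and DESeq2, run on all fibroblasts, called 126, 13, 97 and 208. The atrial cluster 8 alone held 1, 0, 2 and 3 called genes. Shares of the 15 clusters gave 0 of 30 tests past an adjusted p of 0.05 by the exact permutation test. The 400 arrangements allow no p below 0.005, so a single cluster could not pass after adjustment over 30 tests. Cluster 3 stood at that limit, 0.861 points lower with HFpEF (exact permutation p = 0.005, adjusted p = 0.15). Cluster 8 fell by 0.475 points without passing (exact permutation p = 0.045, adjusted p = 0.655). The cluster of the lymphoid class was led by the B-cell genes Pax5 and Bank1.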
